A study of Mus musculus with 8 samples.

How the data were processed

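Platelet RNA from 8 male mice aged 13 weeks was measured by RNA sequencing. The labels give 4 mice as heterozygous for Dnmt3a, the gene of a de novo DNA methyltransferase, and 4 as wild type, and describe the mice as littermates. Per the labels, whole blood was drawn by cardiac puncture, platelets were pelleted out of platelet-rich plasma, and beads against Ter119 and CD45 removed red cells and leukocytes. Stranded libraries of polyadenylated RNA were made with an Illumina kit, per the labels' protocols. The labels call the samples biological replicates, and each mouse gave 1 library. How the mutant allele was made is not given in the sources used here.

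The deposited tables hold an estimated count and a TPM (transcripts per 1000000, corrected for gene length) for every gene and library. The estimated counts that the authors deposited are written as whole numbers, and the deposited TPM values sum to 1000000 in each library. Per the submitters' processing notes, cutadapt, STAR, RSEM and DESeq2 were used with the mouse build mm10. The notes give no role, order or version for these tools, and neither the annotation release nor the strand setting of the counting is given in the sources used here. The estimated counts were rounded to whole numbers before testing, which changed nothing in values already whole. A gene's estimated count depends on how reads shared between near-identical genes were divided, so haemoglobin genes, ribosomal protein genes with processed pseudogenes and other multigene families carry that uncertainty. Genes were named by the symbols in the tables, and 86 missing symbols were looked up by identifier in GENCODE M21 for GRCm38, the build also called mm10. That annotation holds 55141 of the 55487 identifiers, and all coordinates come from it.

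Total counts ran from 15185218 to 22160394 per library, and the library labelled Dnmt3a+/- replicate 4 was the deepest. In every pair of libraries, counts differed by far more than sampling noise (lowest chi-square per degree of freedom 12.2), so each library was counted as 1 replicate. The fit was made with edgeR 4.0.16 under R 4.3.3, with TMM factors, filterByExpr by group (minimum count 10, minimum total 15), glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over the 7362 genes kept, at a threshold of 0.05. Log2 fold changes are the libraries labelled Dnmt3a+/- minus WT, and each standard error was taken from the fold change and its F value. The common dispersion was 0.0613, a biological coefficient of variation of 0.248, and the median standard error of a log2 fold change was 0.22. Levels per library are CPM, counts per 1000000 counts of the library after TMM scaling, given as mean ± SD.

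The groups, the tests, 31 gene lists and the rule for named genes were fixed before the data were examined. The lists cover platelet functions, DNA methylation and its known target classes, immune and metabolic programmes, and other cell types that such a preparation could hold. Each list with at least 5 tested members was tested with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over 26 lists, with the estimated correlation and fry given beside it. The rule for named genes took Dnmt3a, then the genes past the threshold with the largest changes. Since fewer than 5 genes passed, it took the 5 smallest unadjusted p-values in each direction. One gene among those lower is not reported here. It also took up to 2 members per list and direction with an unadjusted p under 0.05, and a fixed set of marker genes given as levels. Gene models named only by clone or prediction were counted and not named by the rule. Shares of counts were compared on the log2 scale, after adding 0.5 counts, with an exact two-sided permutation test over 70 arrangements, whose smallest p is 0.0286. These shares were adjusted over 10 measures. Their 95% Wilson intervals cover counting error only. Neighbours of Dnmt3a were compared with other genes by a two-sided Fisher exact test.

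The scripts were tested on simulated data drawn from the real means, dispersions and library sizes. In 5 simulations of the comparison over 7362 genes, each with 200 changed genes, the test recovered 10.4% of genes changed 1.5-fold, 46.9% of those changed 2-fold and 87.0% of those changed 4-fold, and it called 32 unchanged genes. A simulated shift of 0.3 in the platelet activation signalling list was called in 5 of 5 runs, with 1 call of another list, and no shift was called in 0 of 5. Simulated genes were drawn independently of each other. In the real libraries list members correlated, at an estimated 0.036 for this list and 0.81 for mitochondrially encoded genes. The simulated rates of list calls therefore do not carry over to the real lists. The rates for single genes hold for 200 changed genes among independent genes with the estimated dispersions. They do not measure the power of the real comparison.

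The alternatives fixed beforehand were RLE and upper-quartile factors, no filter on low counts, a strict filter (5 CPM in 4 libraries), DESeq2 1.42.0, a robust quasi-likelihood fit, and limma on log2(TPM + 1) and log2(TPM + 0.1), with TPM of at least 1 in 4 libraries or unfiltered. They further included the replicate number as a block, leaving out haemoglobin and mitochondrial genes, an erythroid or leukocyte covariate, leaving out each library in turn, and wider or narrower windows around Dnmt3a. Lists of hepatocyte and adipocyte genes, a hepatocyte covariate alone and without WT replicate 1, shares from members outside the platelet lists, and neighbours at unadjusted p were added after the data were seen. Fits without WT replicates 3 and 4, the libraries with the most hepatocyte counts, and without the libraries labelled Dnmt3a+/- replicates 3 and 4, chosen by their Dnmt3a level, were run as well. They are not used here, since libraries chosen by a measured level are not groups of the study.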

Results

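Gene expression was measured in platelets from 4 mice labelled Dnmt3a+/- and 4 labelled WT. Platelets are anucleate blood cells shed by megakaryocytes, and their RNA is inherited from those cells. The study's title places the comparison in work on DNMT3A and the megakaryocyte bias of blood stem cells, so the question here is how the platelet transcriptome differs when 1 copy of Dnmt3a is labelled as lost. Total counts were 16005639, 17274175, 17398666 and 15185218 in WT replicates 1 to 4, and 15620972, 15884630, 16634973 and 22160394 in the libraries labelled Dnmt3a+/- replicates 1 to 4. Of 55487 genes in the tables, 7362 had enough counts to be tested.

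Dnmt3a itself (chromosome 12, 3806007 to 3914443, plus strand, GRCm38; ENSMUSG00000020661) was at 20.3 ± 1.70 CPM (counts per 1000000 after TMM scaling) in the WT libraries and 16.3 ± 6.73 in those labelled Dnmt3a+/- (SD, n = 4 each). The WT libraries held 21.1, 22.1, 19.8 and 18.2 CPM, from 332, 408, 315 and 279 counts. The libraries labelled Dnmt3a+/- replicates 1 and 2 held 9.96 and 11.5, from 151 and 186 counts, below all 4 WT values. The libraries labelled Dnmt3a+/- replicates 3 and 4 held 24.2 and 19.5, from 399 and 450 counts, inside or above the WT range. The group difference was a log2 fold change of -0.31 (SE 0.25), smaller than the spread between replicates (edgeR adjusted p = 0.998). Dnmt3a transcript level therefore does not match the label in 2 of the 4 libraries labelled Dnmt3a+/-, and every direction given below is between labels. A mutant allele that still yields a transcript need not lower the count, which would leave the low replicates 1 and 2 unaccounted for, and the kind of allele is not given in the sources used here. The maintenance methyltransferase Dnmt1 was at 0.76 ± 0.40 and 1.03 ± 0.15 CPM in WT and the other group (SD, n = 4). Dnmt3b had 0 to 2 counts and Tet2, a gene of DNA demethylation, had 1 to 6 counts per library, both below the filter.

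**Figure D1:**
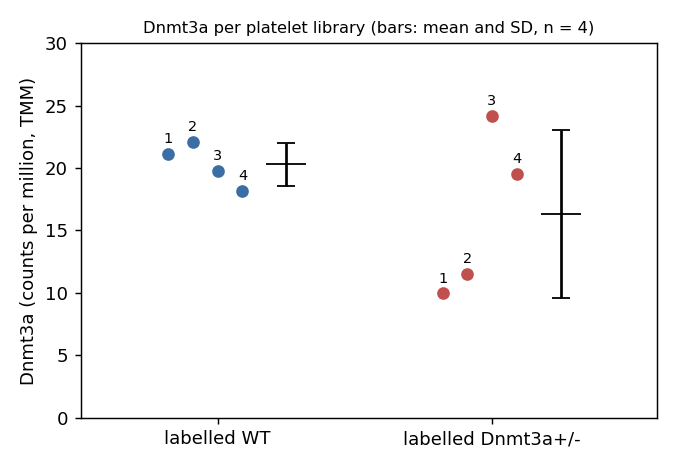
Dnmt3a in CPM after TMM scaling (y axis) in each platelet library, by label (x axis), with the replicate number above each point and the mean and SD of 4 libraries as bars. Replicates 1 and 2 labelled Dnmt3a+/- sit at 9.96 and 11.5, below the 4 WT libraries, and replicates 3 and 4 sit at 24.2 and 19.5.

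The main platelet transcripts had like levels under both labels. Ppbp, a chemokine of the alpha granule, was at 17489 ± 1349 CPM in WT and 18517 ± 940 in the libraries labelled Dnmt3a+/-, and Pf4, platelet factor 4, at 5408 ± 409 and 5636 ± 665 (SD, n = 4). Itga2b, the alpha chain of the fibrinogen receptor, was at 8253 ± 1381 and 7766 ± 1662, Tubb1, the platelet beta tubulin, at 2601 ± 366 and 2789 ± 271, and Vwf, von Willebrand factor, at 3823 ± 724 and 3353 ± 785. The receptor subunits Gp9 and Gp1bb were at 1386 ± 565 and 386 ± 124 in WT, and at 1294 ± 529 and 326.3 ± 123.5 in the other group. The log2 fold changes of these 7 genes ran from -0.24 (Gp1bb, SE 0.27) to 0.10 (Tubb1, SE 0.12), each with an edgeR adjusted p of 0.998.

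No gene passed the adjusted threshold. The edgeR test gave 0 of 7362 genes, against 362 at an unadjusted p under 0.05 (127 higher and 235 lower) where chance alone gives 368.1, and the smallest adjusted p was 0.128. limma on log2 TPM values gave 0 genes, DESeq2 gave 15, all lower in the libraries labelled Dnmt3a+/-, and a robust edgeR fit gave 1 (Cdo1). In 2.54% of genes the 4 values of one label did not overlap the 4 of the other, where chance gives 2.86%. The count depended on the filter and on 1 library. Without a filter on low counts edgeR gave 250 genes, of which 246 were lower, and without WT replicate 1 it gave 135, of which 134 were lower. The 250 held 33 of 39 hepatocyte genes, the 135 held 20 of 37 tested and the 15 of DESeq2 held 0 of 39, from a list chosen after the data were seen. The list holds only some liver genes, so 0 of 39 does not set the 15 apart from the hepatocyte genes. In log2 CPM over the 8 libraries, 70 of the 135 correlated with Alb, serum albumin, at over 0.9. For the 15, all among the 135, this correlation ran from 0.41 (Scd1) to 0.95 (Adh1).

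Genes with small p-values among the lower ones included enzymes of liver and fat metabolism. Cdo1, cysteine dioxygenase, was at 3.85 ± 1.21 CPM in WT and 0.75 ± 0.26 in the libraries labelled Dnmt3a+/- (log2 fold change -2.33, SE 0.32, edgeR adjusted p = 0.128). Scd1, stearoyl-CoA desaturase, had a log2 fold change of -2.35 (SE 0.44), Mgst1, a microsomal glutathione transferase, -3.39 (SE 0.70), and Car3, a carbonic anhydrase abundant in fat, -2.25 (SE 0.47). Their edgeR adjusted p-values were 0.639, 0.647 and 0.647. Scd1 went from 59.3 ± 20.7 to 11.7 ± 9.37 CPM (SD, n = 4). The share of counts from 39 hepatocyte genes, a list chosen after the data were seen, was at 0.132% ± 0.119 in WT and 0.0103% ± 0.0109 in the other group. These shares overlapped, with WT replicate 1 at 0.0037% and the libraries labelled Dnmt3a+/- replicates 1 and 3 at 0.018% and 0.022%. WT replicate 1 still held Cdo1 at 3.57 CPM, Scd1 at 45.2 and Car3 at 11.9, against at most 0.998, 25.7 and 4.52 in the other group. Mgst1 was at 1.21 there, inside the 0.50 to 1.25 of the other group. The share of 24 adipocyte genes, a list also chosen after the data were seen and holding Scd1 and Car3, was at 0.0158% ± 0.0044 and 0.0069% ± 0.0022. Scd1 gave 667 to 1405 of its 1557 to 3598 counts in the WT libraries, and without Scd1 the labels overlapped (0.0059% to 0.0144% and 0.0038% to 0.0071%). DESeq2 gave an adjusted p of 2.6e-06 to Cdo1, its smallest, and of 0.00028 to Ces1d. Scd1 and Mgst1 also passed with DESeq2, at an adjusted p of 0.0218 each, and Car3 did not.

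Among higher genes, the smallest p-values belonged to Vsig10l (log2 fold change 1.04, SE 0.25), Mospd1 (0.97, SE 0.27), Ccl5 (0.66, SE 0.19), Rab9 (0.54, SE 0.16) and Zfp521 (0.64, SE 0.20). Each had an edgeR adjusted p of 0.647, so none passed. Ccl5, a chemokine that platelets store and release, was at 5.90 ± 0.62 CPM in WT and 9.30 ± 2.19 in the libraries labelled Dnmt3a+/-, and the 4 values of each label did not overlap (SD, n = 4). Rab9, a small GTPase of late endosomes, was at 4.72 ± 0.56 and 6.87 ± 0.90. Vsig10l and Mospd1 lay near 1 and 2 CPM.

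The 6 lists of platelet and megakaryocyte functions had medians near 0. Of 31 tested genes of alpha granule cargo, 11 had positive and 20 negative log2 fold changes (median -0.07). Within it, Fn1, fibronectin, and Serping1, the C1 inhibitor, both also made by liver, had values of -1.46 (SE 0.59) and -1.43 (SE 0.60). The median was 0.03 for 29 genes of dense granules and secretion, -0.0043 for 37 surface receptors, 0.02 for 53 activation signalling genes, -0.02 for 51 genes of cytoskeleton and shape, and 0.03 for 23 megakaryocyte transcription factors. The receptor and cytoskeleton medians changed sign with upper-quartile factors, to 0.018 and 0.00025. The ADP receptor P2ry1 was at 59.6 ± 5.78 and 72.4 ± 7.78 CPM, Cd47 at 376 ± 23.2 and 433.2 ± 19.15, and the phospholipase Pla2g4a at 60.1 ± 6.39 and 75.2 ± 10.99 (SD, n = 4), with log2 fold changes of 0.28, 0.20 and 0.32. Parva, an adaptor of integrin adhesion, was at 1.94 ± 0.14 and 1.06 ± 0.58. In these 6 lists 0 members passed over all genes in the main fit and 0 when adjusted over the list alone. Fn1 passed without a filter on low counts (-1.44, edgeR adjusted p = 0.023) and without WT replicate 1 (-1.81, edgeR adjusted p = 0.038). The camera adjusted p ran from 0.289 to 0.948.

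Genes of DNA methylation and of its known target classes gave no list call. Of 13 other genes of the methylation machinery, 8 had positive values (median 0.04, camera adjusted p = 0.340), among them Uhrf2 (log2 fold change 0.75, SE 0.28), a reader of modified cytosine, and Zbtb33 (0.71, SE 0.31), a binder of methylated DNA. For 19 imprinted genes the median was -0.0022 (camera adjusted p = 0.739). Only 2 of the germline genes with methylated promoters were expressed enough to be tested. The median of 16 stem and progenitor genes was -0.07 (camera adjusted p = 0.773), with Mllt3 at 109 ± 9.37 and 137 ± 25.4 CPM and Txnip at 7.96 ± 2.24 and 5.16 ± 1.54 (SD, n = 4). In none of these lists did a member pass over all genes or adjusted over the list alone.

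Only 1 of the 26 tested lists passed, the mitochondrially encoded genes. Of 15 tested members 13 had negative log2 fold changes (median -0.60, camera adjusted p = 0.0003), and 0 passed singly in the main fit. With an estimated correlation of 0.81 between members the list did not pass (adjusted p = 0.906), nor with fry (adjusted p = 0.826). mt-Nd2 and mt-Nd6, subunits of respiratory complex I, had values of -1.34 (SE 0.57) and -1.62 (SE 0.65), with WT levels of 3064 ± 3212 and 18.1 ± 21.1 CPM (SD, n = 4). Without a filter on low counts both passed singly, at -1.31 (edgeR adjusted p = 0.020) and -1.59 (edgeR adjusted p = 0.0135). WT replicate 3 had 24.8% of its counts in mitochondrially encoded genes, and the other 7 libraries 16.7% to 18.96%. Without that library the median was -0.0075 and the list did not pass (camera adjusted p = 0.678). The nuclear genes of oxidative phosphorylation had a median of -0.06 over 71 members (camera adjusted p = 0.340), with Ndufb5 at -0.76 (SE 0.23) and Uqcrb at -0.53 (SE 0.23).

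No list of immune genes passed. Of 39 interferon-stimulated genes 27 had negative values (median -0.16, camera adjusted p = 0.122), among them the GTPase Iigp1 (-2.16, SE 0.61) and the tetherin gene Bst2 (-0.70, SE 0.25), while Ifit1bl1 was at 0.38 (SE 0.17). Of 15 genes of MHC class I and antigen processing 12 were negative (median -0.14, camera adjusted p = 0.213). For 12 inflammatory response genes the median was 0.01 (camera adjusted p = 0.773), with Il1rap at -1.01 (SE 0.32) and Nfkb1 at -1.02 (SE 0.42). The interferon median was 0.018 under a strict expression filter and 0.0049 without WT replicate 1, and the list passed without WT replicate 4 or without the library labelled Dnmt3a+/- replicate 4. These calls are at the preset correlation of 0.01. Over all 8 libraries the estimated correlation was 0.18 (camera adjusted p = 0.946), and fry gave an adjusted p of 0.826.

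The lists of basic cell functions did not pass. The medians were -0.03 for 78 cytosolic ribosomal proteins, -0.04 for 53 translation factors, -0.06 for 18 genes of glycolysis, -0.10 for 40 proteasome genes, -0.0028 for 15 genes of intrinsic apoptosis, -0.01 for 9 cell cycle genes, -0.03 for 21 replication-dependent histones and 0.01 for 9 immediate early and heat shock genes. The camera adjusted p ran from 0.289 to 0.948, and 0 members passed over all genes or adjusted over the list alone. Members with an unadjusted p under 0.05 were all lower and included Rpl13 (-0.38, SE 0.16), the initiation factor subunit Eif3i (-1.07, SE 0.33), Eif2a (-0.96, SE 0.42), Psmc4 (-0.43, SE 0.17) and Rrm1 (-0.81, SE 0.29).

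**Figure D2:**
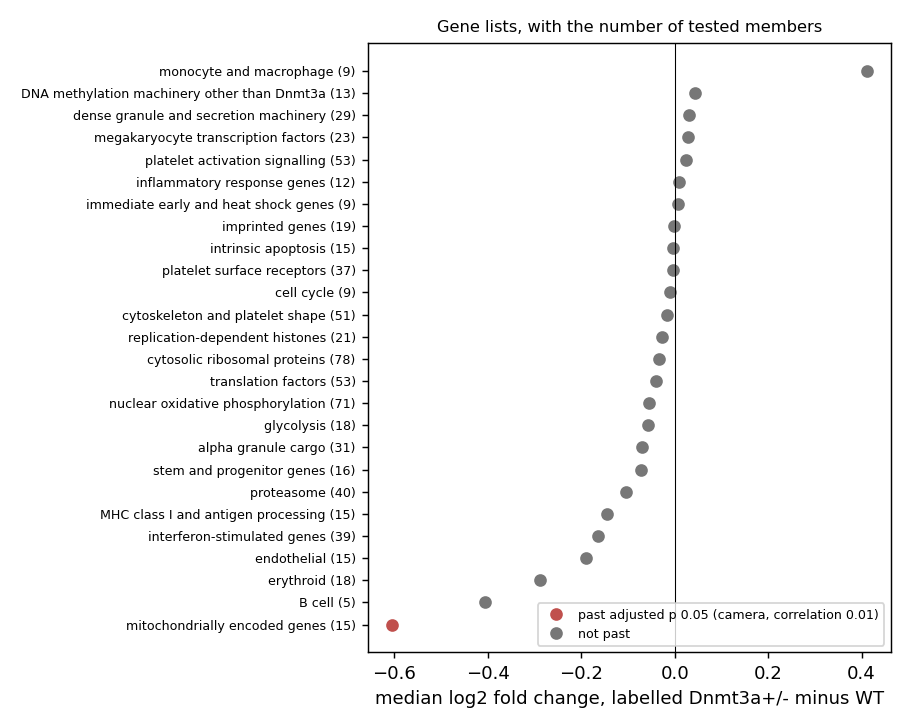
Median log2 fold change of the tested members (x axis, libraries labelled Dnmt3a+/- minus WT) for each of 26 gene lists (y axis, number of members in brackets), coloured by whether the list passed with limma camera at a correlation of 0.01. Only the mitochondrially encoded genes passed, at -0.60, and the 6 lists of platelet and megakaryocyte functions lie between -0.07 and 0.03.

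Transcripts of red cells set 1 library apart. The erythroid list took 2.55% of counts in WT replicate 1 and 0.75% to 1.01% in the other 7 libraries. Alas2, the enzyme that starts haem synthesis in red cells, was at 431 CPM in WT replicate 1 and 6.87 to 7.53 in the other WT libraries, and Hbb-bs, a beta-globin gene, at 8080 and 241 to 293. Group means were 2220 ± 3907 and 491 ± 126 for Hbb-bs, and 2127 ± 1378 and 1982 ± 572 CPM for the alpha-globin gene Hba-a1 (SD, n = 4), whose reads can be shared with near-identical Hba-a2. Without WT replicate 1, Hbb-bs was the 1 gene that passed as higher (log2 fold change 0.88, edgeR adjusted p = 0.038). With all 8 libraries and no filter on low counts it passed as lower (-2.18, edgeR adjusted p = 0.034). In that fit Alas2 (-2.81) and the red cell gene Bpgm (-2.24) passed as lower too, each with an edgeR adjusted p of 0.0167. The erythroid list had a median of -0.29 over 18 genes (camera adjusted p = 0.773). It changed sign without WT replicate 1, to 0.21 (camera adjusted p = 8.5e-05 at the preset correlation of 0.01). Over all 8 libraries the estimated correlation of this list was 0.31 (camera adjusted p = 0.946), and that setting was not run without the library. Bpgm, which makes 2,3-bisphosphoglycerate in red cells, had a log2 fold change of -2.24 (SE 0.98), and Hemgn, a nuclear protein of blood cell precursors, 0.83 (SE 0.26).

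Transcripts of neutrophils, B cells, and T and NK cells were scarce under both labels. Cd3e had 0 counts in all 8 libraries. Counting error alone allows up to 3 expected counts in a library taken singly, and fewer per library over all 8 together. Cd79a had 0 to 4 counts, S100a8 had 1 to 9, and Ptprc, the gene of CD45, had 4 to 27. The shares of the neutrophil, B cell, and T and NK cell lists reached at most 0.0050% of counts in a library. The neutrophil list was lower in the libraries labelled Dnmt3a+/- (0.00033% ± 0.00015 against 0.0011% ± 0.00064, exact permutation p = 0.0286, adjusted p = 0.286), in 4 of 4 libraries against each WT value. Hp, haptoglobin, also a liver product, gave 22, 90, 286 and 159 of the list's 81, 143, 343 and 196 counts in WT replicates 1 to 4, and 47, 4, 16 and 7 of 68, 76, 24 and 62 in the other group. Without Hp the counts overlapped, at 59, 53, 57 and 37 and at 21, 72, 8 and 55. Hp passed when adjusted over the list alone (log2 fold change -2.95, SE 0.82), out of 2 tested. The T and NK cell list had 3 tested members, among them Cd28 at 0.26 (SE 0.11), with 0 past adjusted over the list alone. Cd28 gave 470 of the 643 counts of that list in WT replicate 1. The monocyte and macrophage list took 0.661% ± 0.183 and 0.598% ± 0.128 of counts (exact permutation p = 0.543, adjusted p = 0.857) and shares F13a1 with the platelet lists, with Lyz2, lysozyme, at 4644 ± 1344 and 4039 ± 904 CPM. Without F13a1 the share was 0.462% ± 0.128 and 0.406% ± 0.080. Lyz2 gave 103615 of the list's 149107 counts in WT replicate 1, so F13a1 and Lyz2 made up most of the share there. The 9 tested genes of the monocyte and macrophage list had a median of 0.41 (camera adjusted p = 0.739). The 5 tested B cell genes had a median of -0.41 (camera adjusted p = 0.267), with the MHC class II gene H2-Aa at -1.53 (SE 0.60). All 25 genes of that list took 0.00063% ± 0.00021 and 0.00072% ± 0.00053 of counts (exact permutation p = 0.943, adjusted p = 0.971).

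Of 3 tested genes of basophils and mast cells, Hdc, the enzyme that makes histamine, passed when adjusted over the list alone, at 4.69 ± 0.25 and 3.06 ± 0.47 CPM (log2 fold change -0.62, SE 0.17, edgeR adjusted p over all genes 0.647). Of 15 endothelial genes 14 had negative values (median -0.19, camera adjusted p = 0.108), with Eng at -0.75 (SE 0.33). The endothelial list holds 4 genes of the platelet lists, among them Vwf. With them it took 0.577% ± 0.099 and 0.530% ± 0.078 of counts, and without them 0.0083% ± 0.0015 and 0.0070% ± 0.00095. Of the heart muscle list 1 gene was tested (0.08). Its share was 0.00025% ± 0.00009 and 0.00056% ± 0.00028 of counts (exact permutation p = 0.114, adjusted p = 0.381), with Myl2 at 0 to 4 counts in WT and 0 to 28 in the other group, and Actc1 at 0 to 4 and 2 to 26. Without a filter on low counts the heart muscle list passed, higher (median 1.68, camera adjusted p = 3.3e-06), and the neutrophil list, which holds Hp, passed, lower (median -1.64, camera adjusted p = 0.033). Both are at the preset correlation of 0.01, and an estimated correlation was not run without the filter. With 10 shares and a smallest p of 0.0286, no share could pass after adjustment unless at least 6 reached that p, and none passed (exact permutation tests, adjusted p from 0.286 to 0.971), including the 10 most abundant genes, which took 30.03% ± 1.92 and 30.6% ± 0.49 of counts (SD, n = 4).

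**Figure D3:**
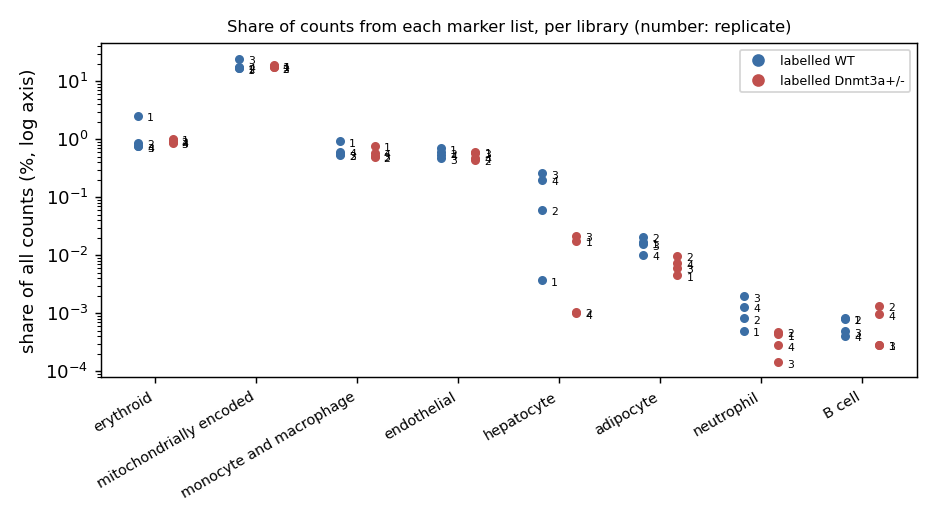
Share of all counts, in percent on a log axis (y axis), that each marker list (x axis) took in each library, with the replicate number beside each point and colours for the 2 labels. WT replicate 1 stands at 2.55% for erythroid genes, WT replicate 3 at 24.8% for mitochondrially encoded genes, and the hepatocyte share runs from 0.0010% to 0.260%. The endothelial share includes 4 genes of the platelet lists, and the monocyte and macrophage share includes F13a1.

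Genes next to Dnmt3a were compared with the rest of the genome because a targeted allele can carry flanking sequence from another strain. Dnmt3a lies near the start of chromosome 12, so a window of 200 protein-coding genes on either side held 204 genes, of which 84 were tested. By the edgeR adjusted p, 0 of these 84 and 0 of 6702 other protein-coding genes passed. At an unadjusted p under 0.05 there were 4 of 84 (4.76%) and 337 of 6702 (5.03%; Fisher exact p = 1), and no excess was detectable with this number of genes.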

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

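The tests in this part were chosen after the results were seen, except the counts over other splits of the libraries. Among 134 groups of 4 values, 13 held a library farther from the other 3 than Dixon's 95% limit allows, where chance gives about 6.7, or 1 in 20.

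The library labelled Dnmt3a+/- replicate 4 had 22160394 counts against 15620972 to 16634973 in the other 3. WT replicate 1 stood apart in erythroid genes, with 2.55% of counts against 0.755% to 0.872%. In that library Alas2 was at 431 CPM against 6.87 to 7.53, Hbb-bs at 8080 against 241 to 293, and Bpgm at 158 against 5.74 to 9.47. It also had the highest Gp1bb, at 569 against 300.4 to 338 CPM. The library labelled Dnmt3a+/- replicate 1 had the highest Bpgm of its group, at 15.6 against 7.18 to 7.99, the highest Cd28 at 41.2 against 36.1 to 36.4, the highest Hdc at 3.76 against 2.78 to 2.91, and the lowest Nfkb1 at 0.20 against 0.67 to 0.74. Scd1 was at 25.7 in the library labelled Dnmt3a+/- replicate 2 against 6.13 to 7.52, and Vsig10l at 2.49 in replicate 3 against 1.82 to 1.86. WT replicate 3 had 24.8% of counts in mitochondrially encoded genes against 16.7% to 17.8% in the other WT libraries.

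The mitochondrially encoded genes were lower in the libraries labelled Dnmt3a+/- as a list, but without WT replicate 3 the list median was -0.0075 (camera adjusted p = 0.678), so the call may rest on that library alone. RNA from liver cells in that library, which had the highest hepatocyte share of 0.260%, is not settled by WT replicate 4, with 0.202%. The mitochondrial share of WT replicate 4 was 17.8%, inside the 16.7% to 18.96% of the other 6 libraries. That share is largely the ribosomal RNA genes mt-Rnr2 and mt-Rnr1 (means of 8.26% and 5.09% of counts). The named members mt-Nd2 and mt-Nd6 were at 2211 and 11.2 CPM in WT replicate 4, above the 761 to 1715 and 3.31 to 8.60 of those 6, so this explanation stays open. With the mean log2 level of the hepatocyte genes as a covariate the median was 0.038 and the list did not pass, but this covariate correlates with the label at 0.65 and would absorb that library's difference whatever its cause, so it does not settle the point. In all 35 splits of the 8 libraries at least 1 list passed, and the highest other split gave 11 lists against 1 for the labels, so chance cannot be excluded. What set WT replicate 3 apart, and a biological difference between mice, stay open and untested.

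Dnmt3a stood at the WT level in the libraries labelled Dnmt3a+/- replicates 3 and 4. A swap of labels between the groups would need a WT library at the lower level, but the lowest WT value was 18.2 CPM, above the 11.5 and 9.96 of replicates 2 and 1. Counting error around a level of 0.5 times the WT mean would give 401 counts over both libraries, against 849 found, with a 95% Poisson interval of 793 to 908. Transcripts from leukocytes left after the CD45 depletion would bring Ptprc with them, but Ptprc reached 1.22 CPM before TMM scaling in these libraries and 1.70 in another. Wrong labels of both libraries with no partner among these mice (1 wrong label would cover 1 of them), and a difference between mice in how much transcript the alleles yield, stay open, untested.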

How the results depend on the processing

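The settings with a hepatocyte covariate, the members outside the platelet lists and the neighbours at unadjusted p were chosen after seeing the data. Dnmt3a kept a negative log2 fold change in all 23 alternatives that gave one, from -0.55 to -0.054, and did not pass in any (smallest adjusted p 0.793). Counts of genes were 0 with RLE and upper-quartile factors, the strict filter, limma on TPM values, the replicate block, haemoglobin and mitochondrial genes left out, and the erythroid, leukocyte and hepatocyte covariates. Without a filter there were 250 genes, 4 higher and 246 lower, of which 116 were also tested with the filter, and 1 call among neighbours of Dnmt3a. DESeq2 gave 15 genes, 15 lower, all of them among the 135 found without WT replicate 1, and the robust fit 1 gene, 1 lower (Cdo1). Leaving out 1 library at a time gave 0 to 135 genes, 0 to 1 higher and 0 to 134 lower, with 0 to 1 calls among neighbours. The 135 came without WT replicate 1, 1 gene (Scd1) passed without the library labelled Dnmt3a+/- replicate 2, and the other 6 fits gave 0. With the hepatocyte covariate and no WT replicate 1, 4 genes passed, 4 lower (Fasn, Car3, Acaca and Me1, named for their values). In that fit the covariate and the label correlated at 0.84, so their effects are hard to separate. The cause of these changes was not tested.

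The mitochondrially encoded genes were the 1 list past in the main setting. Without a filter 1 of the 26 lists passed, and so did the heart muscle and neutrophil lists, too small to test with the filter. There were 0 lists with an estimated correlation and with fry. There were also 0 with haemoglobin and mitochondrial genes left out, but that setting removes the mitochondrially encoded list itself and so does not test it. There were 2 under the strict filter (with ribosomal proteins), 2 with the erythroid covariate and 2 with the replicate block (each with endothelial genes), 4 with the hepatocyte covariate (interferon-stimulated, MHC class I, erythroid and B cell genes), and 10 with that covariate and no WT replicate 1. The mitochondrially encoded genes were not among those 4 and 10, and over 8 libraries the covariate and the label correlated at 0.65. All these calls are at the preset correlation of 0.01, and the estimated correlation was run in the main setting only. Leaving out 1 library gave 0 (without WT replicate 3) to 4 lists (without WT replicate 4, with interferon-stimulated, ribosomal protein and endothelial genes). Ribosomal protein and nuclear oxidative phosphorylation genes passed without the library labelled Dnmt3a+/- replicate 1. Monocyte and macrophage and endothelial genes passed without replicate 3 of that label, and interferon-stimulated and B cell genes without its replicate 4. Erythroid genes passed without WT replicate 1. These calls too are at the preset correlation. Same-numbered libraries correlated at -0.037, 0.081, 0.158 and -0.168 in their deviations within each label, and not every library correlated best with its own number. This showed no pairing by replicate number, but with 4 libraries per label, some set apart by single features, it cannot exclude one. The replicate block gave 0 genes. Counts of shares past the threshold were 0 in every alternative, but over 10 measures the exact test could pass a share only if at least 6 reached its smallest p.

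Of 1893 alternative values, 152 changed sign, and in 12 of these the value passed the threshold in the main or the other setting. Values are log2 unless given as percentages, and the cause was not tested. Hba-a1 was at 0.11 in each limma setting on TPM (log2(TPM + 1), log2(TPM + 0.1) and unfiltered). With upper-quartile factors, list medians that changed sign were surface receptors 0.018, cytoskeleton genes 0.00025, imprinted genes 0.024, intrinsic apoptosis 0.021 and cell cycle genes 0.014. Without a filter, list medians that changed sign were surface receptors 0.00058, imprinted genes 0.012, cell cycle genes 0.17, histones 0.0068 and immediate early genes -0.018. Under the strict filter, list medians that changed sign were stem and progenitor genes 0.13, methylation machinery -0.022 and interferon-stimulated genes 0.018. With the replicate block, the gene that changed sign was Hba-a1 0.061. List medians there were inflammatory genes -0.047 and immediate early genes -0.0064. With the erythroid covariate, genes that changed sign were Alas2 0.52, Gp9 0.10, Hba-a1 0.28 and Hbb-bs 0.36. List medians there were surface receptors 0.041, cytoskeleton genes 0.033, imprinted genes 0.0035, inflammatory genes -0.061, ribosomal proteins 0.011, nuclear oxidative phosphorylation 0.0012, glycolysis 0.028, intrinsic apoptosis 0.011, cell cycle genes 0.029, histones 0.012, immediate early genes -0.012 and erythroid genes 0.076. With the leukocyte covariate, list medians that changed sign were dense granule genes -0.0059, megakaryocyte factors -0.011, imprinted genes 0.011, inflammatory genes -0.030, intrinsic apoptosis 0.0073 and cell cycle genes 0.049. With the hepatocyte covariate, genes that changed sign were mt-Nd6 0.25, mt-Nd2 0.25 and Dnmt1 -0.15. List medians there were dense granule genes -0.0047, imprinted genes 0.066, inflammatory genes -0.036, mitochondrially encoded genes 0.038, histones 0.0079, immediate early genes -0.054 and monocyte and macrophage genes -0.31. With the hepatocyte covariate and no WT replicate 1, genes that changed sign were P2ry1 -0.051, Ifit1bl1 -0.0056, Rpl13 0.042, Bpgm 1.22, Alas2 1.79, Hp 0.051, Itga2b 0.50, Gp1bb 0.85, Gp9 1.01, Vwf 0.48, Hba-a1 0.78, Hbb-bs 1.32 and Lyz2 0.45. List medians there were alpha granule cargo 0.11, surface receptors 0.14, cytoskeleton genes 0.29, megakaryocyte factors -0.023, methylation machinery -0.067, imprinted genes 0.057, inflammatory genes -0.086, ribosomal proteins 0.40, nuclear oxidative phosphorylation 0.32, glycolysis 0.27, histones 0.38, immediate early genes -0.93, erythroid genes 0.62 and monocyte and macrophage genes -2.31. As differences of median percentages, the erythroid share was 0.12 and the mitochondrial share 0.50.

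Over fits that leave out 1 library, genes with a change of sign ranged as Bpgm -2.60 to 0.39, Alas2 -3.20 to 1.17, Itga2b -0.20 to 0.030, Gp1bb -0.49 to 0.0047, Gp9 -0.33 to 0.19, Hba-a1 -0.34 to 0.43, Hbb-bs -2.55 to 0.88 and Lyz2 -0.36 to 0.016. List medians ranged as alpha granule cargo -0.13 to 0.034, dense granule genes -0.023 to 0.083, surface receptors -0.033 to 0.052, cytoskeleton genes -0.054 to 0.057, megakaryocyte factors -0.051 to 0.066, methylation machinery -0.050 to 0.10, imprinted genes -0.018 to 0.052, interferon-stimulated genes -0.33 to 0.0049, inflammatory genes -0.17 to 0.087, ribosomal proteins -0.14 to 0.045, nuclear oxidative phosphorylation -0.13 to 0.036, glycolysis -0.13 to 0.067, intrinsic apoptosis -0.036 to 0.058, cell cycle genes -0.13 to 0.094, histones -0.18 to 0.045, immediate early genes -0.18 to 0.047, erythroid genes -0.39 to 0.21, B cell genes -0.50 to 0.048 and monocyte and macrophage genes -0.086 to 0.66. Log2 shares ranged as erythroid -0.35 to 0.23, B cell -0.48 to 0.26, monocyte and macrophage -0.27 to 0.047, mitochondrially encoded genes -0.12 to 0.074 and the 10 most abundant genes -0.0075 to 0.068.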

Other observations

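The tests in this part were chosen after the results were seen, except the counts over other splits of all 8 libraries. Transcripts of hepatocytes led the first principal component of log2 CPM over the 8 libraries (41.5% of variance). Alb, serum albumin, had 110, 3890, 15123 and 11691 counts in WT replicates 1 to 4, and 935, 4, 1474 and 6 in the libraries labelled Dnmt3a+/- replicates 1 to 4. The hepatocyte share was 0.0037%, 0.061%, 0.260% and 0.202% in WT, and 0.018%, 0.0011%, 0.022% and 0.0010% in the other group, with Wilson intervals no wider than 0.0024 percentage points to either side. Other abundant liver products followed, with Mup3 at 14, 387, 1845 and 1123 counts in WT and 68, 0, 90 and 0 in the other group, and Apoa1 at 7, 182, 711 and 552 and then 36, 1, 76 and 0. Of 32 tested hepatocyte genes all 32 had negative log2 fold changes (median -3.75), with 0 past the threshold over all genes. Of the 39 members 1, Hp, is also in a list fixed earlier, and 2, Apoh and Trf, were at 1 CPM or more in all 8 libraries.

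A second set, 11 tested adipocyte genes, had negative values throughout (median -1.56), with 0 past the threshold over all genes. Of the 24 members 1, Fabp4, is in a list fixed earlier, and 7 were at 1 CPM or more in all 8 libraries. The adipocyte share was 0.017%, 0.021%, 0.016% and 0.010% in WT, and 0.0046%, 0.0098%, 0.0061% and 0.0073% in the libraries labelled Dnmt3a+/-. Without Scd1, whose lower level was seen before the list was chosen, it was 0.0123%, 0.0144%, 0.0074% and 0.0059% in WT and 0.0038%, 0.0071%, 0.0055% and 0.0065% in the others, with overlap. Adipoq, adiponectin, had 25, 39, 8 and 0 counts in WT and 0, 1, 1 and 0 in the others. Scd1, Cdo1 and Car3, lower in the libraries labelled Dnmt3a+/- without passing in the main fit, are expressed in both liver and fat. Without a filter on low counts each of them passed (edgeR adjusted p = 2.3e-06, 3.7e-05 and 2.1e-05), and with DESeq2 Scd1 and Cdo1 did.

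RNA from liver cells carried into some libraries, which beads against Ter119 and CD45 would not remove, is a candidate explanation of the hepatocyte pattern. The median SD over the 8 libraries of log2(gene/Alb) was 1.83 for 31 genes, against 2.97 for the log2 levels themselves, with the smaller SD in 23 of the 31 and not in the other 8. This argues against changes independent between genes, but the list was chosen after hepatocyte genes were seen to be lower. The ratios were not fixed, and a joint change with the genotype would give ratios of the same kind. The hepatocyte share gave an exact permutation p of 0.114 between labels, which decides nothing for a list chosen in this way. Within WT the share ran from 0.0037% to 0.260%. WT replicate 1 lay below the libraries labelled Dnmt3a+/- replicates 1 and 3, at 0.018% and 0.022%. This spread within labels argues against the labelled genotype as the only source. A part played by the genotype cannot be told apart from carry-over. Of the 135 genes past the threshold without WT replicate 1, 20 were among the 37 hepatocyte genes tested, which this choice of list favours. Of the same 135, in and outside that list, 70 correlated with Alb at over 0.9 over the 8 libraries. In 1 of the 35 splits of those 7 libraries, the labelled one, there were as many as 135 genes, and the highest other split gave 0, but this fit was picked from the 8 that leave out 1 library, of which 6 gave 0 genes, so chance is not excluded.

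With all 8 libraries chance cannot be excluded. The labelled split gave 0 genes past the edgeR threshold and 0 calls among the neighbours of Dnmt3a, which all 35 splits match by construction, so these counts test nothing. The highest other splits gave 102 genes and 0 neighbours, the 102 in the split that set WT replicates 1 and 2 with the libraries labelled Dnmt3a+/- replicates 1 and 3 against the rest. At an unadjusted p under 0.05 the labels gave 362 genes, 11 of 35 splits gave as many and the highest other gave 1393. Without a filter on low counts 5 of 35 splits gave as many as the 250 of the labels, the highest other 301, and with DESeq2 8 of 35 gave as many as 15, the highest other 542. The 102, 1393 and 542 came from the same split, which points to a structure of the libraries across the labels. Without a filter, the 4 splits above the labels instead set WT replicate 1 with 3 libraries labelled Dnmt3a+/- against the rest, and so follow the labels but for 1 library of each.

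Of the 250 genes past the threshold without a filter, 4 were higher in the libraries labelled Dnmt3a+/-, and they are named here because of their values. Gm7993, a processed pseudogene on chromosome 5 (95974240 to 95975623), had 120, 144, 153 and 106 counts in WT replicates 1 to 4, and 770, 624, 118 and 183 in the libraries labelled Dnmt3a+/- replicates 1 to 4. Gm9260, a processed pseudogene on chromosome 12 (115982263 to 115993370), had 8, 25, 19 and 8 counts, and then 82, 58, 19 and 26. Reads of a pseudogene can be shared with its parent gene. 4930486L24Rik had 98, 68, 207 and 387 counts in WT and 148, 357, 465 and 2049 in the others. Myl2, a heart muscle myosin gene, had 0, 4, 0 and 0 counts, and then 28, 8, 0 and 21.

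The estimated count of Dnmt3a divided by its TPM, a ratio that follows the effective length given to the gene, differed between libraries. On the log2 scale, relative to the library's median gene and to the gene's mean, it was 0.16, 0.045, 0.032 and 0.34 in WT replicates 1 to 4, and -0.33, 0.35, -0.13 and -0.46 in the libraries labelled Dnmt3a+/- replicates 1 to 4. Its range of 0.81 was larger than that of 96.9% of the 2903 genes with at least 100 counts in each library. In TPM, Dnmt3a was at 7.11, 8.91, 6.41 and 5.6 in WT and at 4.67, 3.52, 10.1 and 10.9 in the others, so in the TPM table replicates 3 and 4 lie above all 4 WT libraries.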
